A study of Danio rerio with 12 samples.

How the data were processed

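Total RNA was sequenced from zebrafish of strain background AB, as whole embryos at 25 hpf (3 sibling and 3 tet2/tet3 double mutant libraries) and as hearts dissected by hand at 48 hpf (2 libraries each of wild type, sibling and double mutant). Per the labels' protocols, embryos were staged by morphology and heart RNA was amplified before library construction. Per the labels, the sibling group pooled wild type animals with heterozygotes for tet2, tet3 or both. The deposited tables hold raw counts per gene for each library, and these counts were used for every test; columns of normalised values beside them were not used. The authors also deposited a log2 fold change and a p-value with an adjusted p-value per gene for each pairwise comparison, and per the file headers these stand beside the counts of the same libraries. The tool behind them is not named in the files. In the authors' heart tables against WT the log2 fold change is WT over the other group, and its sign is turned here. STAR 2.3.0e, HTSeq 0.6.0 and the genome build GRCz10 are named per the submitters' processing notes, without the role of each. Gene coordinates come from the deposited tables, and the build was not checked against a genome sequence. Each table holds 25680 genes, 25672 protein coding and 8 polymorphic pseudogenes, so non-coding transcripts were not analysed here. Identifiers are given where several genes share a symbol (421 symbols).

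Samples were grouped by the labels alone. Total counts ranged from 8341467 to 16700992 in embryo libraries and from 3289161 to 5963478 in heart libraries, and the 95% intervals given for ratios of low counts cover counting error only. The limit for a count of 0 was set at 3 counts per library. The labels do not say that libraries of a group came from separate clutches, so p-values measure the spread between these samples, which may be technical. The main tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

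Counts were normalised by TMM, filtered with filterByExpr and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the Benjamini-Hochberg FDR at 0.05. The 6 embryo libraries formed a fit, and the 6 heart libraries formed another with a shared spread for the 3 groups. The difference of DM effects between hearts and embryos was tested as an interaction contrast over 10 libraries, with a spread shared by both tissues. Gene lists were tested with camera (two-sided, correlation preset at 0.01, adjusted over the lists of a comparison), and again with a correlation estimated from the data and with fry (limma 3.58.1). Neither of these called any list in any comparison, so every camera call depends on the preset correlation. Of 1102 members of the 28 lists, 1075 were found. Several members are expressed in more than 1 tissue, and lists share members. Log2 fold changes given with an SE come from edgeR, also where a DESeq2 adjusted p stands beside them. The SE is the absolute log2 fold change divided by the square root of the edgeR F statistic. Group levels are mean CPM with SD.

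Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2 size factors and upper quartile factors in edgeR, no filter on low counts, stricter thresholds, fits on the compared groups only, quality weights, each library left out in turn, and the replicate number in the labels as a block. The block is used in the text for embryos because equally numbered libraries deviated from their group means alike (correlations across genes of 0.847, 0.672 and 0.270, each above the minimum of 0.1), although the labels do not state a pairing and the differently numbered sibling replicate 2 and DM replicate 3 had 0.512, above pair 3. After the data were seen, fits were added that removed a smooth trend of each library with the genomic span of genes (lowess, span 0.3), left out a pair of embryo libraries, or left out the sibling and DM hearts numbered 1, which held lens transcripts.

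Named genes were tet1, tet2 and tet3. Then came the genes of each comparison with FDR under 0.05, mean CPM of at least 5, groups that did not overlap and a proper symbol, up to 10 per direction by log2 fold change (5 for sibling against WT and for the interaction), filled up to 5 by the smallest p where fewer passed. Up to 3 members of each list with the smallest p completed the set. As the main tests called few genes, the same rule was also applied to the blocked embryo calls and to the DESeq2 calls, a step decided after the data were seen. Some genes that this rule named are not reported here.

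The tests were also tried on simulated data with the depth and spread of these libraries, with 100 genes changed per fold. In the embryo design edgeR recovered 12 of the genes changed 2-fold and 87 changed 4-fold, with 9 calls among the unchanged of 17629 genes, DESeq2 recovered 32 and 91 with 26 such calls among 17831, and limma-voom 10 and 86 with 5. The blocked edgeR fit recovered 93 and 100 with 8 such calls among 17621 genes. In the heart design edgeR and limma-voom recovered 0 and 0 (1 and 2 such calls among 16387 genes), and DESeq2 recovered 3 and 39 with 37 such calls among 16998. For the interaction edgeR recovered 0 and 9 with 1 such call among 19340 genes, DESeq2 1 and 30 with 9 among 19689, and limma-voom 0 and 6 with 1. A simulated list of 30 genes changed 2-fold was called by camera in each design, and 0 of 28 other lists were. Genes were simulated independently of each other, so this does not show how often camera calls lists whose members are correlated.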

Results

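RNA was sequenced from 12 zebrafish libraries at 2 stages to ask how the loss of tet2 and tet3 alters gene expression in the early embryo and in the developing heart. Both genes encode TET dioxygenases, which oxidise 5-methylcytosine in DNA. Double mutants (DM) carried inactivating mutations in both genes, and their siblings were a mixture of wild type animals and tet2 and/or tet3 heterozygotes. Whole embryos at 25 hours post fertilisation (hpf) gave 3 sibling and 3 DM libraries. Hearts dissected by hand at 48 hpf gave 2 libraries each from wild type (WT), sibling and DM animals, numbered 1 and 3 in every group. Embryo libraries held 8341467 to 16700992 counted reads and 21985 to 22601 detected genes, and heart libraries held 3289161 to 5963478 reads and 20115 to 21853 detected genes. The 10 most abundant genes took 7.50% to 8.41% of the counts in embryos and 6.56% to 10.8% in hearts. A count of 0 allowed a level of up to 0.180 to 0.360 CPM (counts scaled to library size) in an embryo library and 0.503 to 0.912 CPM in a heart library.

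Transcripts of all 3 tet genes were present in every library, mutant libraries included. In embryos, tet2 (ENSDARG00000076928, chromosome 1, 25662646 to 25693594, GRCz10) was counted at 120, 77.7 and 114 CPM in the sibling libraries and at 152, 97.2 and 87.5 CPM in the DM libraries. For tet3 (ENSDARG00000062646, chromosome 5, 13809699 to 13826742) the levels were 94.96, 48.4 and 74.6 CPM in sibling embryos and 92.1, 35.0 and 38.0 CPM in DM embryos. The third paralog, tet1 (ENSDARG00000075230, chromosome 13, 18066195 to 18165134), stood at 19.8, 10.1 and 16.0 CPM in siblings and at 16.9, 7.67 and 9.97 CPM in mutants. In hearts, tet2 was counted at 141 and 351 CPM in WT, at 251 and 167 CPM in siblings and at 139 and 167 CPM in DM. Heart levels of tet3 were 96.3 and 95.5 CPM in WT, 119 and 68.5 CPM in siblings and 110 and 119 CPM in DM. Heart levels of tet1 were 44.8 and 74.5 CPM in WT, 61.4 and 44.6 CPM in siblings and 45.1 and 48.5 CPM in DM. None of the 3 passed the edgeR test in any comparison. In embryos the log2 fold changes (DM over sibling) were 0.18 (SE 0.25, adjusted p = 0.768) for tet2, -0.35 (SE 0.37, adjusted p = 0.724) for tet3 and -0.34 (SE 0.31, adjusted p = 0.722) for tet1. Counts per gene do not show whether a transcript encodes an inactive protein. With the replicate numbers as a block the adjusted p values were 0.471, 0.0829 and 0.129 in the same order, and tet2 reached 0.00111 when the pair of libraries numbered 3 was left out.

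Lens genes were among the most reduced genes in DM embryos. The structural crystallins cryba1b (ENSDARG00000053875, chromosome 21, 39140703 to 39149628) and crygn2 (ENSDARG00000030411, chromosome 24, 41441956 to 41449024) fell from 17.3 ± 14.3 and 18.6 ± 10.2 CPM in siblings (mean ± SD, n = 3) to 0.646 ± 0.192 and 2.07 ± 0.433 CPM in mutants. Their log2 fold changes were -4.58 (SE 0.28, adjusted p = 5.07e-11) and -3.00 (SE 0.21, adjusted p = 3.45e-10) in the edgeR fit that used the replicate numbers in the labels as a block. The lens aquaporin mipa (ENSDARG00000037285, chromosome 23, 27141684 to 27146233) fell from 16.2 ± 11.0 to 1.97 ± 0.856 CPM (log2 fold change -2.90, SE 0.22, adjusted p = 1.17e-09). Further crystallins that fell in the same fit were crybb1l1 (-4.24, adjusted p = 6.52e-11), crybb1l2 (-3.45, adjusted p = 5.07e-11), crybb1 (-3.05, adjusted p = 8.69e-07) and cryba4 (-2.42, adjusted p = 2.58e-07). Of the 16 measured members of the lens and retina list, 9 fell and 1 rose in the blocked fit, or 11 and 1 when adjusted over the list alone. As a group they were lower than other genes, with a median log2 fold change of -1.01 (camera, adjusted p = 1.09e-09; adjusted p = 0.387 with an estimated correlation). Within the pairs of equally numbered libraries the list median was -0.97, -0.62 and -1.42.

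Genes outside the lens also fell in DM embryos. The retinoic acid hydroxylase gene cyp26b1 (ENSDARG00000077121, chromosome 7, 25052585 to 25077440) fell from 51.4 ± 5.09 to 16.1 ± 2.88 CPM (n = 3, log2 fold change -1.61, SE 0.15, adjusted p = 1.32e-07). The neuronal membrane glycoprotein gene gpm6aa (ENSDARG00000055455, chromosome 14, 36008235 to 36038180) dropped from 137 ± 24.1 to 43.8 ± 1.98 CPM (-1.56, SE 0.16, adjusted p = 2.58e-07). The transcription factor gene npas1 (ENSDARG00000015876, chromosome 15, 8448640 to 8541484) dropped from 10.4 ± 4.096 to 1.29 ± 0.194 CPM (-2.89, SE 0.26, adjusted p = 3.79e-08). The actinodin genes and1 and and2, which encode fibre proteins of the fin fold, had log2 fold changes of -2.74 (SE 0.24, adjusted p = 2.57e-08) and -2.73 (SE 0.38, adjusted p = 6.13e-05). Among the genes that rose, ca9 (ENSDARG00000102300, chromosome 10, 6413482 to 6453356), which encodes a hypoxia-responsive carbonic anhydrase, went from 2.67 ± 0.956 to 12.2 ± 1.34 CPM (2.3002, SE 0.21, adjusted p = 5.58e-08). The vitamin D hydroxylase gene cyp24a1 rose by 1.61 (SE 0.20, adjusted p = 7.98e-06), and the bHLH repressor gene her3 rose by 1.42 (SE 0.17, adjusted p = 3.57e-06). The homeobox gene irx7 rose by 1.17 (adjusted p = 2.64e-05), the chemokine scavenger receptor gene ackr3a by 1.28 (adjusted p = 6.51e-05) and the MFAP4 family member ENSDARG00000093877 by 1.71 (adjusted p = 2.8e-07).

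**Figure D1:**
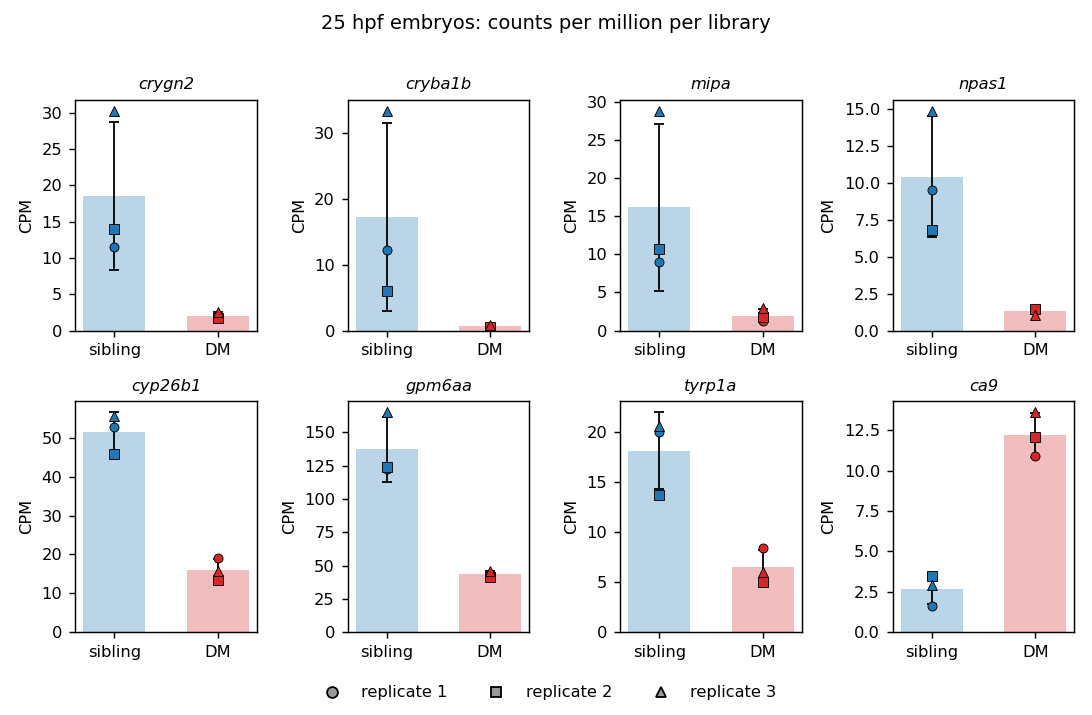
Levels of 8 genes in 25 hpf embryos on a CPM axis. Bars are group means, error bars are the SD (n = 3) and each point is a library, with the marker showing its replicate number. All 3 DM libraries lie below all 3 sibling libraries for crygn2, cryba1b, mipa, npas1, cyp26b1, gpm6aa and tyrp1a, and above them for ca9.

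The blocked edgeR fit called 2453 of 17831 genes at a false discovery rate (FDR) of 0.05, of which 779 were higher and 1674 lower in DM. The main test, which had no block, called 0 genes by edgeR, with 585 at an unadjusted p under 0.05, and 0 by limma-voom. The DESeq2 test without a block called 39 genes (8 higher and 31 lower), of which 36 were among the blocked calls. The authors' deposited table called 47 genes, 11 higher and 36 lower, and listed cyp26b1 with a log2 fold change of -1.45 and an adjusted p of 4.94e-12. Each gene named above had an adjusted p of at least 0.191 in the edgeR test without a block. With each pair of equally numbered libraries left out in turn the blocked fit called 536, 1227 and 3119 genes, in the order of pairs 1 to 3. Without sibling replicate 2, the edgeR test without a block called 2 genes.

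Part of the list of pigment cell and neural crest genes fell in DM embryos in the blocked fit. Of 36 measured members, 16 fell and 0 rose in the blocked fit (20 and 0 adjusted over the list alone), and the list median was -0.47 (camera, adjusted p = 1.75e-07; adjusted p = 0.387 with an estimated correlation). The melanin synthesis genes tyr, tyrp1a and dct had log2 fold changes of -1.56 (SE 0.18, adjusted p = 2.31e-06), -1.40 (SE 0.17, adjusted p = 7.37e-06) and -0.98 (SE 0.15, adjusted p = 0.00021). The crest and cartilage factor sox9b fell by 1.41 (adjusted p = 6.13e-05). Neural progenitor and neuron genes had a median of -0.32 over 57 members (camera, adjusted p = 2.31e-06; adjusted p = 0.576 with an estimated correlation), with 14 members lower and 1 higher (20 and 1 over the list alone). They included the eye field gene rx1 (-1.30, adjusted p = 9.66e-05) and the proneural gene neurod4 (-1.03, adjusted p = 0.00031). Notch pathway genes had a median of -0.25 over 33 members (camera, adjusted p = 0.005; adjusted p = 0.387 with an estimated correlation). The receptors notch1a and notch1b and the ligand jag1a were among the 11 that fell, by 1.16, 1.03 and 0.96, and 1 member rose (14 and 1 over the list alone). Vascular endothelial genes had a median of -0.32 over 32 members (camera, adjusted p = 0.000103; adjusted p = 0.387 with an estimated correlation), with 9 lower and 1 higher (10 and 1 over the list alone). The endothelial receptor gene tek fell by 1.00 (adjusted p = 0.00162), and its adjusted p was 0.0550 without the pair of libraries numbered 1. The 4 lists and the lens and retina list each kept the camera call without any single library.

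Hox cluster genes stood slightly higher in DM embryos, with a median of 0.29 over 48 members, 40 of them positive (camera, adjusted p = 0.000136; adjusted p = 0.576 with an estimated correlation). With the trend of counts with genomic span removed (below), the median was 0.12 and the list was not called (adjusted p = 0.114). The blocked fit called 3 of them higher, among them hoxd12a (0.63, adjusted p = 0.0169; 0.161 and 0.181 without pair 1 or pair 2; 0.0823 with the span trend removed), and 2 were called over the list alone. Cell cycle and replication genes had a median of -0.22 over 55 members (camera, adjusted p = 0.00959; adjusted p = 0.387 with an estimated correlation), with 17 lower in the blocked fit and 22 over the list alone. The helicase gene mcm2 fell by 0.97 (adjusted p = 0.00127) and the checkpoint kinase gene bub1 by 0.85 (adjusted p = 0.00186). The cell cycle call ended without sibling replicate 2 (adjusted p = 0.108). In the list of DNA methylation machinery, 3 of 27 members fell and 1 rose (3 and 1 adjusted over the list alone too), and the list itself was not called (median -0.05, adjusted p = 0.769). The maintenance methyltransferase gene dnmt1 fell by 0.92 (adjusted p = 0.00208), its partner uhrf1 by 0.80 (adjusted p = 0.00468; 0.0525 without pair 1), and the demethylation-associated gadd45ga rose by 0.81 (adjusted p = 0.00262).

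A further 7 lists passed camera in embryos, but each of these calls ended without at least 1 library. Endocardium and valve genes had a median of -0.21 (adjusted p = 0.0294; 0.0662 without sibling replicate 1 and 0.0810 without DM replicate 1), with 6 members lower in the blocked fit. Extracellular matrix genes had a median of -0.19 (adjusted p = 0.0294; 0.399 without sibling replicate 1, 0.109 without DM replicate 2 and 0.0530 without DM replicate 3), with 15 of 92 members lower and 5 higher. Kidney and niche genes stood at -0.45 (adjusted p = 0.017; 0.0767 without sibling replicate 1 and 0.0534 without DM replicate 2). Notochord, cartilage and fin genes stood at -0.32 (adjusted p = 0.0468; 0.307, 0.111 and 0.172 without sibling replicate 1, DM replicate 2 or DM replicate 3), and their 8 members lower in the blocked fit included col11a2 (-1.20, adjusted p = 6.5e-05). Skin genes had a median of 0.28 (adjusted p = 0.00959; 0.0662 without sibling replicate 1 and 0.175 without DM replicate 2), with 5 higher and 2 lower. Genes of the p53 pathway had a median of 0.17 (adjusted p = 0.0468; 0.118, 0.116 and 0.250 without sibling replicates 1 or 2 or DM replicate 3), with 4 members higher. Mitochondrially encoded genes had a median of 0.34 (adjusted p = 0.00982; 0.130, 0.0709 and 0.0519 without sibling replicate 1, DM replicate 2 or DM replicate 3), with 0 of 13 called in the blocked fit. Adjusted over the list alone, members lower and higher in the blocked fit numbered 6 and 1 for endocardium, 20 and 9 for extracellular matrix, 9 and 2 for kidney, 11 and 4 for notochord, 2 and 11 for skin, 0 and 5 for p53 and 0 and 0 for mitochondrial genes. With an estimated correlation, the adjusted p of these 7 lists ranged from 0.444 to 0.63.

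Apart from endocardium, heart lists were not called in embryos, nor were blood lists. Medians were 0.07 for cardiomyocyte genes (adjusted p = 0.408), -0.18 for cardiac transcription factors (adjusted p = 0.158), -0.07 for epicardium (adjusted p = 0.694), 0.00 for haemogenic endothelium (adjusted p = 0.769), -0.05 for erythroid genes (adjusted p = 0.769; 0.000895 and lower without DM replicate 3) and -0.16 for myeloid genes (adjusted p = 0.645; 0.0212 and lower without sibling replicate 1). The band 3 gene slc4a1a of the erythroid list nevertheless fell by 1.63 in the blocked fit (SE 0.16, adjusted p = 2.8e-07). For TGF-beta, activin and BMP genes the median was -0.01 and the mean 0.00, with the test pointing upward (adjusted p = 0.769). For skeletal muscle the median was 0.13 and the mean -0.03 (adjusted p = 0.583; 0.0192 and higher without sibling replicate 1). The remaining adjusted p values were 0.19 for germ cell genes (median 0.11), 0.373 for interferon genes (median 0.08), 0.158 for glycolysis and hypoxia genes (median 0.10; 0.0310 without sibling replicate 1 and 0.0367 without DM replicate 2) and 0.0711 for yolk and liver genes (median 0.19; 0.029 with the block; 0.0484, 0.0493 and 0.0476 without sibling replicate 3, DM replicate 1 or DM replicate 3). Immediate early and heat shock genes had a median of 0.09 and an adjusted p of 0.057, which fell to 0.00774, 0.00457, 0.0172 and 0.0031 without sibling replicates 1 or 3 or DM replicates 2 or 3. The blocked fit called 8 of them higher and 2 lower (9 and 2 adjusted over the list alone), among the higher ones fosab (1.15, adjusted p = 0.00361; 0.0753 without pair 1).

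Embryo libraries also differed in a way the groups did not share. The first principal component held 69.2% of the variance and placed sibling replicates 1 and 3 and DM replicate 1 apart from sibling replicate 2 and DM replicates 2 and 3. Levels followed the genomic span of genes (the distance from gene start to gene end), with correlations across genes of 0.391, -0.313 and 0.248 in the sibling libraries and 0.317, -0.368 and -0.336 in the DM libraries. The DM effect followed span too (r = -0.326 and rho = -0.376 across 17831 genes, which are not independent replicates), with r of -0.230, -0.186 and -0.357 within pairs 1 to 3. Its median ran from 0.238 in the tenth of genes with the shortest span (2.63 kb) to -0.250 in the tenth with the longest (139 kb), and the blocked fit called 4.65% and 18.9% of these genes lower. After a smooth trend with span was removed from each library, the blocked fit called 2325 genes (891 higher and 1434 lower), and 1564 of the 2453 calls (63.8%) stayed in the same direction. List medians then were -1.18 for lens and retina (camera, adjusted p = 8.42e-12), -0.42 for neural crest and pigment (adjusted p = 2.91e-07) and -0.41 for neural genes (adjusted p = 9.71e-08). Notch, vascular and cell cycle lists kept adjusted p values of 0.000116, 0.00022 and 0.00022, whereas without the block Hox (0.114), endocardium (0.0673), extracellular matrix (0.334), kidney (0.0608), notochord (0.0530), skin (0.0775), p53 (0.207) and mitochondrial genes (0.167) were no longer called. With block and trend removal together 9 lists were called, those 6 and notochord (0.00739), kidney (0.0122) and skin (0.0148). With an estimated correlation after trend removal, none of the lists still called passed (without the block, adjusted p = 0.317 for lens, crest, vascular and cell cycle and 0.677 for neural and Notch genes, and with it 0.616 or more for all).

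**Figure D2:**
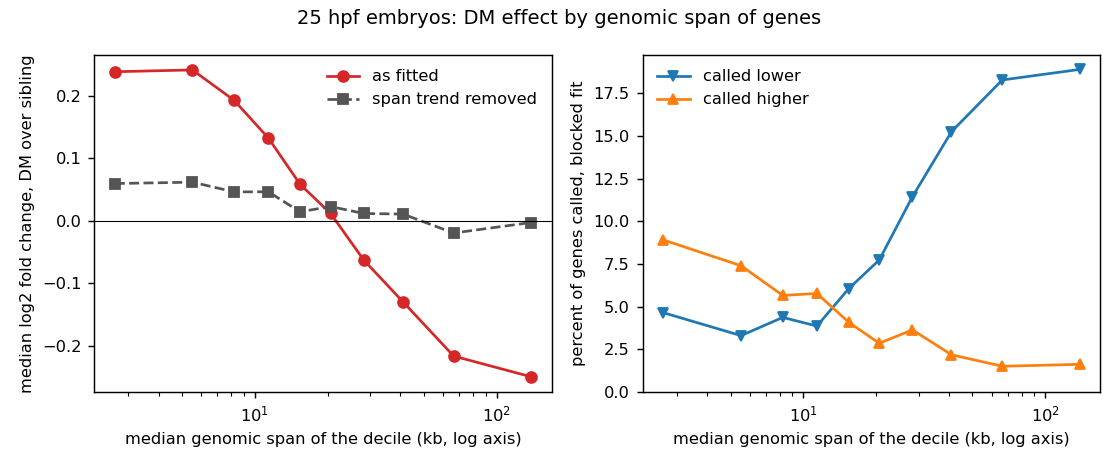
DM effect in embryos by genomic span, in 10 groups of genes of equal number, with span in kb on a log axis. The left plot gives the median log2 fold change as fitted and after the trend with span was removed, and the right plot gives the percent of genes called lower or higher by the blocked fit. The median as fitted runs from 0.238 to -0.250 and the median after removal from 0.0593 to -0.00312.

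Heart libraries held varying amounts of transcripts from other tissues. Cardiomyocyte markers took 10.5% and 5.83% of counts in WT, 3.24% and 6.64% in siblings and 7.15% and 9.23% in DM. Lens and retina markers took 0.390% of sibling replicate 1 and 0.236% of DM replicate 1, against 0.00412% to 0.0265% in the other 4 heart libraries. Skin markers took 0.195% and 0.179% in WT, 0.457% and 0.309% in siblings and 0.388% and 0.449% in DM, and yolk and liver markers 0.130% and 0.108%, 0.438% and 0.212%, and 0.221% and 0.266% in the same order. Skeletal muscle markers took 2.60% of DM replicate 1 and 0.710% to 1.82% of the other heart libraries. Replicates correlated at 0.890 in WT, 0.850 in siblings and 0.872 in DM (log2 CPM across genes), against 0.938 to 0.983 within embryo groups.

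Among the genes that DESeq2 called lower in DM hearts than in sibling hearts were hoxb8a, foxf1 and inhbaa. The homeobox gene hoxb8a (ENSDARG00000056027, chromosome 3, 23557361 to 23559933) stood at 93.4 ± 5.61 CPM in sibling hearts (mean ± SD, n = 2) and at 4.55 ± 3.44 CPM in DM hearts, a log2 fold change of -4.38 (SE 0.66, DESeq2 adjusted p = 4.94e-08). The forkhead gene foxf1 (ENSDARG00000015399, chromosome 18, 30868983 to 30872111), a regulator of visceral mesoderm, stood at 41.6 ± 0.999 and 1.57 ± 0.894 CPM (-4.71, SE 0.76, DESeq2 adjusted p = 6.24e-06). The activin subunit gene inhbaa (ENSDARG00000012671, chromosome 24, 3191762 to 3204082) stood at 37.0 ± 3.11 and 2.49 ± 0.141 CPM (-3.90, SE 0.67, DESeq2 adjusted p = 0.000146). The BMP10 family member ENSDARG00000045632 (chromosome 10, 561903 to 567303) held 6 counts in both DM hearts together and 219 in both sibling hearts, 45.5-fold lower after scaling to depth (95% counting interval 20.6 to 125). The homeobox gene nkx3.3 held 2 and 144 counts, 89.8-fold lower with an interval of 24.4 to 748 (DESeq2 adjusted p = 0.000421). The junction gene jam2b, a marker of the epicardial lineage, stood at 21.8 ± 8.36 and 2.82 ± 0.344 CPM (-2.94, SE 0.49, DESeq2 adjusted p = 0.001). Other genes called lower were foxf2a (-5.11), foxa3 (-2.80), prdm1a (-2.77), BNC1 (-3.87), hnf1ba (-2.93), hoxc1a (-2.81), col12a1a (-2.33) and col6a2 (-2.74), with DESeq2 adjusted p values of 6.24e-06 to 0.00497. In WT hearts hoxb8a, foxf1 and inhbaa stood at 57.6 ± 26.3, 12.5 ± 9.40 and 11.4 ± 8.49 CPM.

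Genes called higher in DM than in sibling hearts were fewer. The embryonic globin gene hbbe3 (ENSDARG00000038147, chromosome 12, 20217539 to 20218669) stood at 48.1 ± 14.1 CPM in siblings and 196 ± 17.2 CPM in DM (n = 2, log2 fold change 2.01, SE 0.36, DESeq2 adjusted p = 0.000986), with 145 ± 16.6 CPM in WT. The erythroid ammonium transporter gene rhag stood at 182 ± 5.41 and 757 ± 217 CPM (2.05, SE 0.40, DESeq2 adjusted p = 0.00113). The vesicular monoamine transporter gene slc18a2 (ENSDARG00000015110, chromosome 17, 23762300 to 23791308) held 310 counts in DM hearts and 9 in sibling hearts, 27.6-fold higher after scaling to depth (interval 14.4 to 61.0; DESeq2 adjusted p = 0.000257). The desmin gene desmb stood at 2.62 ± 1.98 and 57.9 ± 39.3 CPM (4.35, SE 0.80, DESeq2 adjusted p = 4.95e-05), with 19.0 ± 9.34 CPM in WT. DM replicate 1, the heart library with the largest share of skeletal muscle markers, held 466 counts of desmb. DM replicate 3 held 128 and WT replicate 3 held 132. In total DESeq2 called 66 genes, 18 higher and 48 lower in DM, and the authors' deposited table called 103, 26 higher and 77 lower. The main edgeR test called 0 of 16998 genes (568 at an unadjusted p under 0.05, lowest adjusted p 0.723), limma-voom called 0, and edgeR without a filter on low counts called 3. In simulated data with the spread of these hearts, edgeR recovered 0 of 100 genes changed 4-fold, and DESeq2 recovered 39 of 100 with 37 calls among the unchanged genes. Without the lens-bearing libraries (sibling replicate 1 and DM replicate 1), 65 of the 66 genes called by DESeq2 were measured, and 65 kept their direction. The remaining hearts had taken part in those calls.

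**Figure D3:**
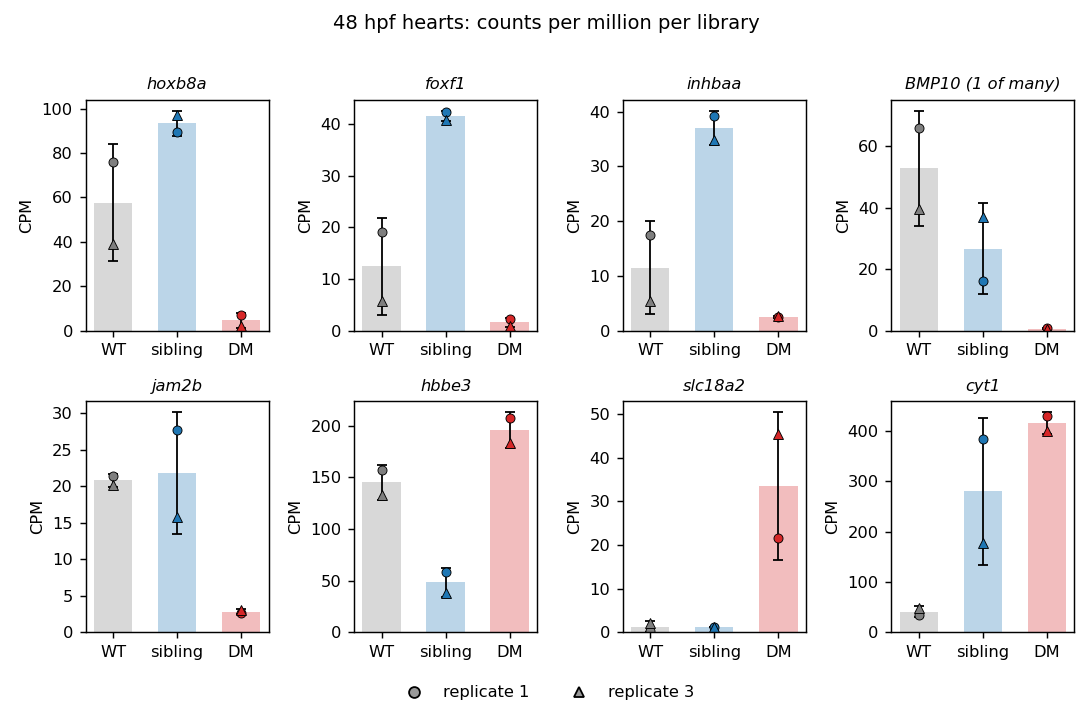
Levels of 8 genes in 48 hpf hearts on a CPM axis. Bars are group means, error bars are the SD (n = 2) and each point is a library, with the marker showing its replicate number. Both DM libraries lie below both sibling libraries for hoxb8a, foxf1, inhbaa, the BMP10 family member ENSDARG00000045632 and jam2b, and above them for hbbe3 and slc18a2.

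The Hox cluster and erythroid lists separated DM from sibling hearts without any single library deciding the call. Of 32 measured Hox genes, 30 were lower in DM, with a median of -1.66 (camera, adjusted p = 6.11e-15; adjusted p = 0.82 with an estimated correlation). DESeq2 called 4 of them lower over all genes and 10 when adjusted over the list alone, and edgeR called 0 and 5. Examples were hoxc1a and hoxa3a (-1.93, DESeq2 adjusted p = 0.0139). Erythroid genes had 20 of 26 members higher and a median of 0.74 (camera, adjusted p = 1.23e-07; adjusted p = 0.82 with an estimated correlation), with 2 called higher by DESeq2 and 4 when adjusted over the list alone. Against WT the picture differed, as Hox medians were -0.59 in DM (adjusted p = 0.288 without DM replicate 3) and 0.81 in siblings (0.401 without sibling replicate 1), and erythroid medians were -0.73 and -1.40. Cardiomyocyte genes were also higher in DM than in sibling hearts, 29 of 31 with a median of 0.73 (camera, adjusted p = 1.77e-08; adjusted p = 0.82 with an estimated correlation), but the adjusted p was 0.190 without sibling replicate 1, the heart library with the smallest share of cardiomyocyte transcripts.

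The other list calls between DM and sibling hearts rested on single libraries. Skeletal muscle genes had a median of 1.25 (adjusted p = 6.8e-07), with 0.203 without sibling replicate 3 and a reversed sign without DM replicate 1 (0.941). Germ cell genes had a median of 0.63 (adjusted p = 0.0216; 0.515 and reversed without sibling replicate 1, 0.210 without DM replicate 1, 0.00473 and reversed without both). Extracellular matrix genes had a median of -0.28 (adjusted p = 0.0337; 0.4999 without sibling replicate 1, 0.330 without DM replicate 1, 0.898 and reversed without both), with 5 members called lower by DESeq2. Yolk and liver genes had a median of -0.58 (adjusted p = 0.00492; 0.875 and reversed without sibling replicate 1, 0.123 without DM replicate 3). Mitochondrially encoded genes had a median of -0.70 (adjusted p = 0.0185; 0.940 and reversed without sibling replicate 3, 0.330 without DM replicate 1). With an estimated correlation the adjusted p of these 5 lists was 0.82 to 0.988.

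Lists of cardiac transcription factors, epicardium and TGF-beta, activin and BMP signalling were not called between DM and sibling hearts. Adjusted p values were 0.536 for cardiac transcription factors (median 0.25), of which prdm1a was called lower by DESeq2, 0.568 for epicardium (median -0.08) and 0.917 for TGF-beta, activin and BMP genes (median -0.03), and no left-out library changed these. DNA methylation genes (median -0.07, adjusted p = 0.536), cell cycle genes (median -0.09, adjusted p = 0.431), interferon genes (adjusted p = 0.653) and myeloid genes (adjusted p = 0.894) were not called either, with or without any library. Endocardium genes had a median of 0.03 and a mean of -0.22 (adjusted p = 0.536; 0.000752 and lower without sibling replicate 1, 0.0332 and lower without DM replicate 3). For lens and retina genes the median was -0.32 and the mean 0.02 (adjusted p = 0.955), and the sign followed the libraries. They were called higher in DM without sibling replicate 1 (1.89e-07) or DM replicate 3 (5.86e-06) and lower without sibling replicate 3 (5.02e-05) or DM replicate 1 (8.67e-07). Neural genes behaved alike (median 0.01, adjusted p = 0.681; higher at 3.67e-09 without sibling replicate 1, lower at 0.000283 without sibling replicate 3).

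Against WT hearts, DM hearts held few transcripts of a BMP10 family member and of jam2b, and more skin keratin transcripts. The BMP10 family member ENSDARG00000045632, of a family that acts in heart wall growth, stood at 52.8 ± 18.7 CPM in WT (n = 2) and at 0.603 ± 0.187 CPM in DM, with 598 and 6 counts (86.8-fold lower, interval 39.7 to 238; log2 fold change -6.68, SE 0.73, DESeq2 adjusted p = 5.77e-11). The separate gene bmp10 (ENSDARG00000061769) stood at 18.5 ± 10.6 CPM in WT, 8.30 ± 6.57 CPM in siblings and 14.6 ± 0.941 CPM in DM. Levels of jam2b were 20.8 ± 0.906 CPM in WT and 2.82 ± 0.344 CPM in DM (-3.17, DESeq2 adjusted p = 0.00019). The connexin gene cx41.8 stood at 40.5 ± 6.77 and 4.48 ± 0.68 CPM (-3.47, SE 0.53, DESeq2 adjusted p = 1.21e-05). The hyaluronan synthase gene has2, needed for endocardial cushions, stood at 261 ± 56.1 and 51.3 ± 7.03 CPM (-2.64, DESeq2 adjusted p = 0.00247). The keratin genes krtt1c19e, cyt1 and krt5 rose from 6.51 ± 0.671, 41.0 ± 11.0 and 21.9 ± 12.2 CPM in WT to 96.4 ± 6.15, 416 ± 21.7 and 161 ± 2.23 CPM in DM. Their log2 fold changes were 3.59, 3.05 and 2.60, with DESeq2 adjusted p values of 3.33e-10, 1.68e-06 and 0.000282. Sibling hearts, at 28.9 ± 6.48, 281 ± 146 and 91.2 ± 5.16 CPM, lay between both groups by their means for these keratins. Also called lower in DM were hoxb8a (-3.97, DESeq2 adjusted p = 9.89e-07), fabp11a (-3.39), tmem88a (-3.46), rspo2 (-3.60), foxf1 (-3.27), prdm1a (-2.96), egr3 (-2.95) and hoxc1a (-2.24), and slc18a2 was called higher (4.50, DESeq2 adjusted p = 0.00042).

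By DESeq2, 120 genes differed between DM and WT hearts, 51 higher and 69 lower. The authors' deposited table called 289, 160 higher and 129 lower. The main edgeR test called 0 (1254 at an unadjusted p under 0.05, lowest adjusted p 0.354), limma-voom called 0, and edgeR without a filter on low counts called 3.

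Skin markers had 33 of 43 members higher in DM than in WT hearts, with a median of 1.16 (camera, adjusted p = 3.81e-06; adjusted p = 0.572 with an estimated correlation). DESeq2 called 4 of them higher and 1 lower over all genes, and 12 and 2 when adjusted over the list alone, and edgeR called 5 and 1 over the list alone. Yolk and liver genes had a median of 0.92 (adjusted p = 0.000475) and germ cell genes a median of 2.43 (adjusted p = 3.96e-06), and he1a of the yolk list rose by 3.84 (DESeq2 adjusted p = 0.0136). Erythroid genes were lower, 22 of 26 with a median of -0.73 (adjusted p = 3.96e-06), including slc4a1a, which fell from 659 ± 9.25 to 209 ± 0.275 CPM (-1.95, DESeq2 adjusted p = 1.94e-05), and the carbonic anhydrase gene cahz (-1.53, DESeq2 adjusted p = 0.00769). Endocardium and valve genes (median -0.65, adjusted p = 6.12e-05) and mitochondrially encoded genes (median -0.81, adjusted p = 0.000311) were lower too. These 6 calls held without any single library, and each had an adjusted p = 0.572 with an estimated correlation. Sibling hearts stood at 263 ± 0.610 CPM for slc4a1a, and at 195 ± 17.8 CPM for cahz against 207 ± 1.75 CPM in DM. By their medians, the skin, yolk and liver, germ cell, erythroid and endocardium lists moved in the same direction in sibling against WT hearts (below). Differences of these lists from WT were therefore not particular to DM hearts.

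Other list calls between DM and WT hearts ended without 1 library, mostly WT replicate 1. Epicardium genes had a median of -1.03 (adjusted p = 0.000425; 0.404 without WT replicate 1), extracellular matrix genes -0.42 (9.86e-06; 0.344 without WT replicate 1, 5 members called lower by DESeq2) and cardiac transcription factors -0.37 (0.00408; 0.831 and reversed without WT replicate 1, 0.0636 without DM replicate 1). TGF-beta, activin and BMP genes had a median of -0.41 (adjusted p = 0.000475; 0.109 without WT replicate 1, 0.0540 without DM replicate 1), and vascular genes -0.58 (0.0008; 0.548 without WT replicate 1, 0.0753 without DM replicate 1). Hox genes had a median of -0.59 (adjusted p = 0.000303; 0.288 without DM replicate 3), with 2 called lower by DESeq2 and 5 over the list alone. Immediate early and heat shock genes stood at -0.85 (2.67e-06; 0.124 without WT replicate 3), myeloid genes at -0.31 (0.0188; 0.409 without WT replicate 3, 0.0654 without DM replicate 3) and neural crest genes at -0.53 (0.0188; 0.409 without WT replicate 3, 0.0843 without DM replicate 3). Glycolysis and hypoxia genes had a median of -0.53 (0.00643; 0.544 without WT replicate 1, 0.179 without DM replicate 3). With an estimated correlation the adjusted p of these 10 lists was 0.572 or 0.594. Cardiomyocyte genes had a median of -0.33 and missed the threshold (adjusted p = 0.0519), and reached 1.82e-05, 0.0245, 0.0194 and 0.012 without WT replicate 3, sibling replicate 1, sibling replicate 3 or DM replicate 3.

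Genes that separated DM hearts from both control groups were counted where both comparisons passed in the same direction. DESeq2 gave 22 genes lower and 2 higher in both. The lower ones included the BMP10 family member ENSDARG00000045632 (but not bmp10), jam2b, hoxb8a, hoxc1a, foxf1, foxf2a, foxa3, nkx3.3, prdm1a, has2, rspo2, egr3 and the collagen genes col6a2 and col12a1a. The higher ones were krtt1c19e and slc18a2. Independent lists of the same lengths would share 0.243 lower and 0.0648 higher genes, and data simulated with unchanged DM hearts gave 4.2 in both directions together. Genes were simulated independently of each other. The simulated overlap therefore does not cover genes that vary together between hearts, such as those of tissue left on at dissection. The authors' deposited table listed 26 genes as lower and 6 as higher in both. The main edgeR test gave 0 (simulated 0.05), and edgeR without a filter gave 1. Log2 fold changes correlated at r = 0.546 across 16998 genes, against 0.492 in simulated data in which only the shared DM libraries linked the comparisons, and the covariance was 0.433 against 0.320. For the 2 comparisons that share the WT hearts, r was 0.648 against 0.497 simulated. Their covariance exceeded the simulated one by 0.241, against 0.113 for the pair sharing DM hearts. With shared sibling hearts r was -0.285 against -0.511. An excess over the simulation was thus not particular to DM hearts. The controls could not be split with 2 libraries in each part, so the shared DM libraries remained in both comparisons.

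Sibling hearts differed from WT hearts in blood, muscle and skin transcripts. Erythroid genes were lower in siblings in 24 of 26 cases, with a median of -1.40 (camera, adjusted p = 1.16e-22; adjusted p = 0.347 with an estimated correlation). DESeq2 called 7 of them lower over all genes and 17 when adjusted over the list alone, and edgeR called 0 and 12. Among them hbbe3 fell from 145 ± 16.6 to 48.1 ± 14.1 CPM (n = 2, log2 fold change -1.88, DESeq2 adjusted p = 0.00946) and nt5c2l1 fell by 1.91 (DESeq2 adjusted p = 0.0165). Cardiomyocyte genes were lower in 30 of 31 cases with a median of -1.07 (camera, adjusted p = 1.28e-13; adjusted p = 0.496 with an estimated correlation), and no single member was called over all genes (0 higher and 2 lower by DESeq2 adjusted over the list alone). Skin genes were higher in 34 of 43 cases with a median of 1.40 (adjusted p = 9.91e-11), and yolk and liver genes in 35 of 44 with a median of 1.27 (adjusted p = 4.14e-11), both with an adjusted p = 0.347 with an estimated correlation. The keratins cyt1 and krtt1c19e rose by 2.49 and 1.88 (DESeq2 adjusted p = 0.00246 and 0.0403), and the apolipoproteins apoa1b and apoc1 by 1.56 and 2.33 (0.0478 and 0.0387). Glycolysis and hypoxia genes had a median of -0.83 (adjusted p = 1.51e-06; adjusted p = 0.496 with an estimated correlation). These 5 list calls held without any single library.

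Between sibling and WT hearts DESeq2 called 50 genes, 37 higher and 13 lower in siblings, and the authors' deposited table called 24, 17 higher and 7 lower. The main edgeR test called 0 of 16998 (833 at an unadjusted p under 0.05, lowest adjusted p 0.913), and limma-voom and edgeR without a filter called 0. The kinase gene prkcq held 220 counts in siblings and 7 in WT (44.97-fold higher after scaling to depth, interval 21.5 to 113; DESeq2 adjusted p = 0.000125), and the matrix gene abi3bpb stood at 12.6 ± 2.19 CPM in WT and 60.0 ± 1.91 CPM in siblings (1.98, DESeq2 adjusted p = 0.0192). Further genes called higher were sparcl1 (3.95) and fut9d (3.58), and genes called lower were the TGFBR2 family member ENSDARG00000059363 (-2.04) and hbae1 (-3.46), with DESeq2 adjusted p values of 0.00535 to 0.0281.

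Further list differences between sibling and WT hearts rested on 1 or 2 libraries. Vascular genes had a median of -0.62 (adjusted p = 1.4e-05; 0.196 without WT replicate 1, 0.0808 without sibling replicate 1), endocardium genes -0.62 (0.000243; 0.0930 without WT replicate 1, 0.204 without sibling replicate 1) and epicardium genes -0.56 (0.000642; 0.587 without WT replicate 1). Cardiac transcription factors stood at -0.58 (5.41e-05; 0.401 without WT replicate 1), TGF-beta, activin and BMP genes at -0.35 (0.000392; 0.160 without WT replicate 1) and extracellular matrix genes at -0.27 (0.00779; 0.401 and reversed without WT replicate 1, 0.554 without sibling replicate 3). Immediate early genes stood at -0.98 (6.86e-09; 0.0841 without WT replicate 3), myeloid genes at -0.70 (0.00431; 0.259 without WT replicate 3), skeletal muscle genes at -0.62 (1.4e-05; 0.343 without sibling replicate 3) and neural crest genes at -0.32 (0.0128; 0.532 without WT replicate 3, 0.682 and reversed without sibling replicate 3). Germ cell genes were higher (1.55, adjusted p = 0.000856; 0.554 and reversed without sibling replicate 3), as were Hox genes in 29 of 32 cases (0.81, adjusted p = 0.000128; 0.401 without sibling replicate 1). With an estimated correlation the adjusted p of these 12 lists was 0.347 to 0.634.

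The DM effect in hearts was then tested against the DM effect in embryos, a contrast in which stage, tissue and library preparation differ together. This fit gave embryos and hearts a shared spread, with a common dispersion of 0.119. Fitted alone, embryos had 0.0731 and hearts 0.234, so heart differences were judged against a smaller spread than in the heart fit. The 9 calls below may lean on the tighter embryo libraries, as the heart fit called 0 genes for DM against sibling. In hearts, 9 genes fell relative to embryos and 0 rose in the main edgeR test (19689 genes, 1161 at an unadjusted p under 0.05). They were hoxb8a (log2 difference -4.55, SE 0.55, adjusted p = 0.0156), foxf1 (-4.47, SE 0.54, adjusted p = 0.0156), barx1 (-5.07, SE 0.62, adjusted p = 0.0156), inhbaa (-4.05, SE 0.52, adjusted p = 0.0203), hoxc1a (-2.86, SE 0.39, adjusted p = 0.0279) and foxf2a (-4.88, SE 0.71, adjusted p = 0.0372). The AEBP1 family member ENSDARG00000006901 (-3.64, SE 0.43, adjusted p = 0.0156), the chemokine gene cxcl12b (-2.80, SE 0.38, adjusted p = 0.0279) and nkx3.3 (-7.42, SE 1.03, adjusted p = 0.0279, with 2 counts in DM hearts) complete the set. These last 3 lay outside the naming rule and were chosen after their values were seen. In embryos the DM effects of the 9 genes lay between -0.55 and 0.88. In hearts, all 9 were lower in both DM libraries than in both sibling libraries, and 8 were also lower than in both WT libraries. The exception was barx1, at 0.388 CPM in WT replicate 3. The margin over DM was small in WT replicate 3 for the AEBP1 family member (18 counts against 16 and 14) and foxf2a (19 against 11 and 11). DESeq2 called 89 genes, 12 higher and 77 lower, the blocked edgeR fit called 48, edgeR with DESeq2 size factors 17 and without a filter 14, and each of these included all 9. Limma-voom called 7 and, with quality weights, 1.

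Single libraries decided many of these interaction calls. With sibling replicates 1, 2 or 3 or DM replicates 2 or 3 of the embryos left out, edgeR called 0 genes, and without embryo DM replicate 1 it called 6. Without heart sibling replicate 1 it called 4, of which 3 were among the 9, and without heart sibling replicate 3 it called 41, with all 9 among them. Without heart DM replicate 1 or 3 it called 16 and 15, with 6 and 5 of the 9. Without both lens-bearing hearts all 9 genes stayed lower in DM than in sibling hearts, with a median log2 fold change of -3.76 against -4.38 with all hearts. With any single library left out the log2 difference of each of the 9 genes stayed negative, the weakest value being -2.65 for cxcl12b. Just short of the threshold lay slc18a2 (5.06, adjusted p = 0.0513; 0.0217 with the block), jam2b (-3.26, 0.0513), foxa3 (-2.85, 0.0577) and prdm1a (-2.72, 0.0606), the last 3 with 0.041 each with the block. For cyp26b1 the difference was 1.87 (adjusted p = 0.278).

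Among the lists, the Hox cluster had the lowest adjusted p in the interaction test. Its DM effect was lower in hearts than in embryos for 42 of 48 members, with a median of -1.35 (camera, adjusted p = 2.87e-15; adjusted p = 0.79 with an estimated correlation), and no left-out library ended this call. Members called lower numbered 2 over all genes and 11 when adjusted over the list alone. Some of the 48 members were too low in hearts for the heart fit and entered through their embryo counts. One was hoxd12a, with 1 and 3 counts in sibling hearts and 3 and 0 in DM hearts. The count of 42 and the median include such members. Erythroid genes were also called (median 0.88, adjusted p = 7.22e-05; 0.0646 without heart sibling replicate 1, 0.0742 without heart DM replicate 3), as were yolk and liver genes (-0.67, adjusted p = 0.000455; 0.574 without heart sibling replicate 1). Cardiomyocyte genes had 0.65 (0.000129; 0.862 without heart sibling replicate 1, 0.0742 without heart DM replicate 3), skeletal muscle genes 1.42 (0.000129; 0.407 without heart sibling replicate 3, 0.845 and reversed without heart DM replicate 1) and mitochondrially encoded genes -0.92 (0.000617; 0.351 without heart sibling replicate 3, 0.0993 without heart DM replicate 1). Neural genes had 0.47 (0.0143; 0.0615 without embryo DM replicate 2, 0.0223 and reversed without heart sibling replicate 3, 0.423 without heart DM replicate 1). Germ cell genes had 0.65 (0.0355; 0.117 and 0.203 without embryo sibling replicate 2 or DM replicate 1, 0.437 and reversed without heart sibling replicate 1, 0.240 without heart DM replicate 1). Skin genes had -0.28 (0.0355; 0.114, 0.157 and 0.0981 without embryo sibling replicate 1 or DM replicates 2 or 3, and 0.949, 0.168 and 0.0742 without heart sibling replicate 1 or DM replicates 1 or 3). Neural crest genes had 0.46 (0.037; 0.0698, 0.130, 0.0992 and 0.0735 without embryo sibling replicates 1 or 3 or DM replicates 2 or 3, 0.405 and reversed without heart sibling replicate 3, and 0.168 and 0.0623 without heart DM replicates 1 or 3). With an estimated correlation all of these had an adjusted p of 0.79.

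Across 15672 genes tested at both stages, the DM effects against siblings were weakly related (r = 0.112, rho = 0.116, 53.9% of genes with the same sign). Genes are not independent replicates, so no p-value is attached. The correlation was 0.184 with the heart effect taken against WT and 0.143 for genes of at least 5 CPM. Without heart sibling replicate 1 it was -0.00986, without heart DM replicate 1 it was 0.0564, and without both it was -0.0570.

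**Figure D4:**
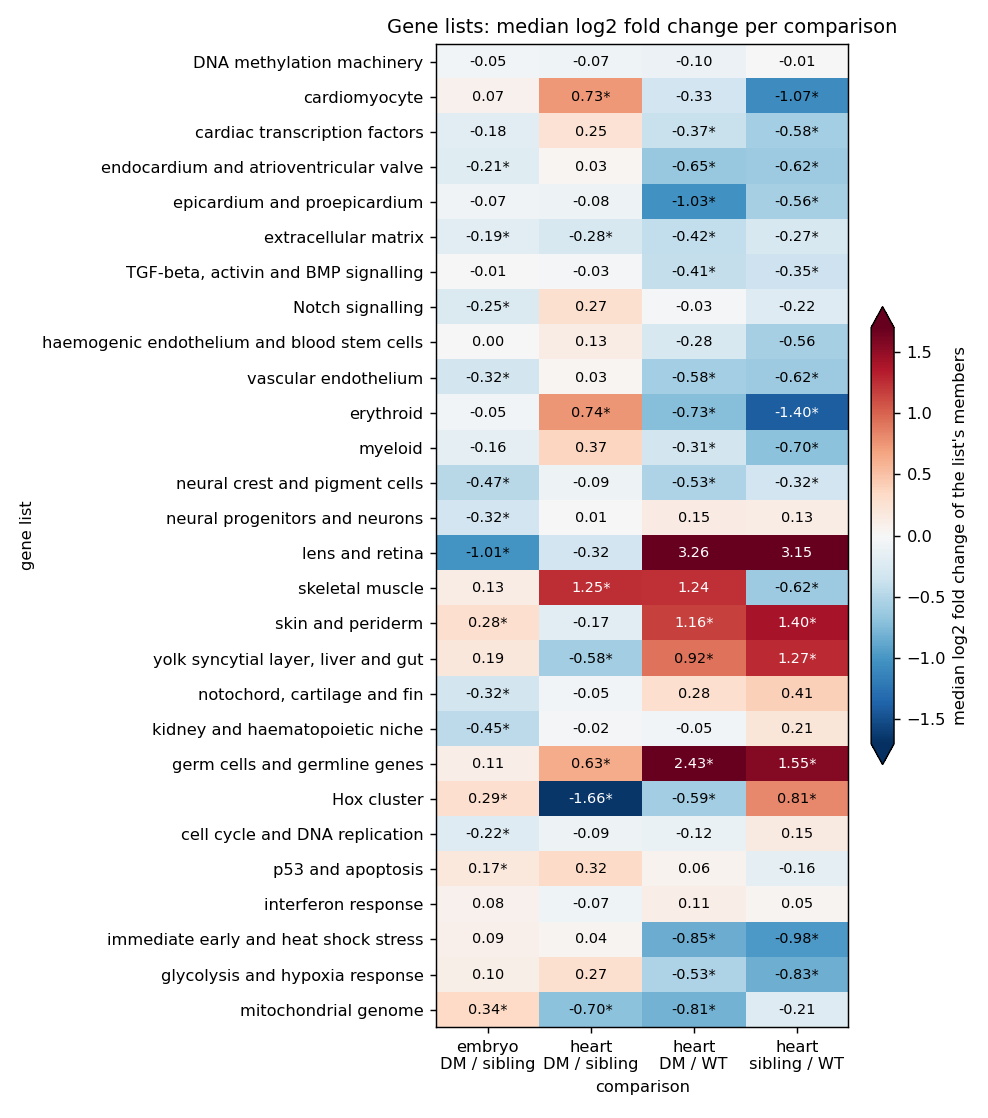
Median log2 fold change of the 28 gene lists in 4 comparisons, with colour for the median (scale limited at 1.7 in either direction) and an asterisk where camera gave an adjusted p under 0.05. Hox genes run from 0.29 in embryos to -1.66 in DM against sibling hearts, and erythroid genes from -1.40 in sibling against WT hearts to 0.74 in DM against sibling hearts.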

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

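The tests in this part were chosen after the result was seen, except the counts of other splits of the embryo libraries, the interaction test and the lists, which were planned.

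The first pattern is the loss of lens, retina and pigment transcripts in DM embryos, within 2453 genes called by the blocked fit. A trend of counts with genomic span as the whole cause is argued against. Once the trend was removed, 63.8% of the blocked calls stayed in the same direction. For pigment and crest genes the ratio of the list medians after and before removal was 0.891. Lens and retina genes are short (median span 7.05 kb), and the trend raised short genes in DM (0.241 in the tenth at 5.52 kb). Its removal could therefore only lower the lens and retina median, which went from -1.01 to -1.18. That change tests nothing further. The 4 splits of the libraries that part all 3 pairs, and the 10 splits without a block, are too few for a share under 0.05 (1 of the 4 splits reached the real count of 2453 with a highest other of 0, and 10 of 10 reached the real count of 0 with a highest other of 9307, for sibling replicates 1 and 3 and DM replicate 1 against the rest, a structure of the samples beyond the groups). A difference in developmental stage between DM and sibling embryos cannot be told apart from an effect of the mutations, since stage was not varied within a group. List means of lens and retina genes ranged over 0.878 log2 units among the siblings, against a DM effect of -1.18 on that mean. Pigment and crest genes ranged over 0.270 against an effect of -0.51. Within pairs 1 to 3 the list medians were -0.97, -0.62 and -1.42 for lens and retina and -0.34, -0.33 and -0.63 for pigment and crest. These values do not separate stage from genotype. The tet2 and tet3 genotype therefore remains an open and untested biological explanation, beside stage.

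The second pattern is the set of 9 genes whose DM effect was lower in hearts than in embryos, all of which differed in the interaction test. They were AEBP1 family member ENSDARG00000006901 (log2 difference -3.64), barx1 (-5.07), inhbaa (-4.05), foxf1 (-4.47), foxf2a (-4.88), cxcl12b (-2.80), hoxb8a (-4.55), nkx3.3 (-7.42) and hoxc1a (-2.86). Whether lens or muscle material in the sibling and DM hearts numbered 1 was the cause cannot be decided from these values. Without both libraries all 9 genes were still lower in DM than in sibling hearts, with a median log2 fold change of -3.76 (median absolute deviation 1.35). With all libraries this median was -4.38 (1.38). DM hearts were also below the WT hearts, with medians of -3.27 with DM replicate 1 and -3.42 without it (median absolute deviations 1.14 and 1.54). The same DM hearts took part in choosing the genes, so lower values there partly follow from the choice. Tissue next to the heart left on in varying amounts stays a candidate explanation, because the same 9 genes were all higher in WT replicate 1 than in WT replicate 3 by a median of 1.697 (median absolute deviation 0.974), whereas the median of all genes was 0.00 and 30 other Hox genes had a median of -0.18. A loss of cells or of expression in mutant hearts, as named by the design, stays open and untested beside it.

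The third pattern is the excess of skin and yolk or liver transcripts in sibling hearts over WT hearts. A smaller share of heart muscle alone is argued against, since markers of other cell types moved apart, with a median of -1.40 for erythroid genes and 1.40 for skin genes. Skin and yolk cells carried along at dissection cannot be told apart from other causes, since 8 of the 10 skin genes and 9 of the 10 yolk and liver genes most abundant in embryos were higher in both sibling hearts than in both WT hearts, which follows from the higher lists whatever the cause, and 6 and 9 of the 10 were higher in both DM hearts too. The most abundant skin gene, krt4, stood at 59.2 and 290 CPM in WT and 1034 and 942 CPM in siblings (663 and 1814 in DM), and apobb.1 at 82.5 and 202 against 977 and 464 CPM (278 and 517 in DM). Heterozygosity for tet2 or tet3 in siblings and the separate crosses behind WT animals stay open and untested.

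Other list effects that passed camera with its preset correlation in the interaction test, none of which passed with an estimated correlation (adjusted p = 0.79 for each) or with directional fry, were erythroid genes (median difference 0.88) and cardiomyocyte genes (0.65). Skeletal muscle genes differed by 1.42, neural genes by 0.47 and neural crest genes by 0.46. Germ cell genes differed by 0.65, skin genes by -0.28 and yolk and liver genes by -0.67. Hox genes differed by -1.35 and mitochondrially encoded genes by -0.92. The Hox difference held without any single library. The others ended without at least 1, with the highest adjusted p being 0.0742 for erythroid genes (heart DM replicate 3), 0.862 for cardiomyocyte, 0.437 for germ cell, 0.949 for skin and 0.574 for yolk genes (heart sibling replicate 1), 0.405 for neural crest and 0.351 for mitochondrial genes (heart sibling replicate 3), and 0.845 for skeletal muscle and 0.423 for neural genes (heart DM replicate 1).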

How the results depend on the processing

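The alternatives chosen after the data were seen are the removal of the span trend, the blocked fits without a pair, and the fits without the sibling and DM hearts numbered 1. Every alternative fixed beforehand was run. Where they leave a group with 1 library, that library is assumed to vary like the other groups.

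For genes called in embryos (0 in the main test) the block gave 2453, DESeq2 39, the block with the span trend removed 2325 and the block without pair 1, 2 or 3 gave 536, 1227 and 3119, while single left-out libraries gave 0 to 2. The blocked fit removes what equally numbered libraries share, and its common dispersion was 0.0161 against 0.0731 without a block. In hearts (0 in each main test) the lack of a filter gave 3 for DM against sibling, 3 for DM against WT and 1 for both controls, and DESeq2 gave 66, 120 and 24, with 50 for sibling against WT. Block, scaling, voom, stricter thresholds and left-out libraries gave 0 in hearts. For the interaction (9) DESeq2 size factors gave 17, no filter 14, the block 48, quality weights 1 and DESeq2 89, and left-out libraries 0 to 41. The correlation of effects between stages (0.112) was 0.184 against WT, -0.0570 without the hearts numbered 1, and -0.00986 to 0.155 over left-out libraries. Beyond fewer samples in left-out fits, the cause was not tested.

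Of 145 gene results over 1872 values, 9 were called in the main test, 0 reversed and 16 never changed. A reversal was counted only where the main result or the alternative was called, so changes of sign without a call are not covered. Scaling shifted the median of all genes by at most 0.063 log2 units. Of 140 list results, 65 were called with all libraries, 39 never changed and 26 reversed under at least 1 of 1680 values. Estimated correlation and fry ended all 65 calls. In embryos the block changed no list call other than that of yolk and liver genes. Elsewhere it made calls of lens genes in DM against WT hearts (0.00907), sibling against WT hearts (0.0168) and the interaction (0.00985) and of cardiomyocyte genes in DM against WT hearts (0.0486), and it ended those of neural crest (0.107) and germ cell genes (0.187) in the interaction. The equally numbered hearts deviated from group means with correlations of 0.30, -0.25 and -0.03.

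Without the hearts numbered 1, reversed adjusted p values in DM against sibling hearts were 0.898 for extracellular matrix, 0.00473 for germ cell and 0.921 for yolk genes. Against WT they were 0.00295 for Notch, 1.80e-06 for lens and 4.46e-11 for skeletal muscle genes in DM, and 1.21e-06 for lens, 2.39e-06 for neural and 0.00926 for notochord genes in siblings. For the interaction they were 0.0451 for germ cell and 0.782 for skin genes.

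Lists that reversed without a single library had these ranges of adjusted p. For DM against sibling hearts they were 2.83e-07 to 0.431 for Notch, 0.0192 to 0.995 for neural crest, 3.67e-09 to 0.4998 for neural, 1.89e-07 to 0.869 for lens, 1.20e-17 to 0.941 for skeletal muscle, 9.42e-06 to 0.875 for yolk, 3.84e-09 to 0.515 for germ cell and 3.97e-07 to 0.940 for mitochondrial genes. For DM against WT hearts they were 2.58e-07 to 0.831 for cardiac transcription factors, 0.000993 to 0.792 for Notch, 3.67e-07 to 0.865 for neural, 2.80e-07 to 0.409 for lens and 1.99e-06 to 0.788 for skeletal muscle genes. For sibling against WT hearts they were 3.20e-07 to 0.554 for extracellular matrix, 3.97e-05 to 0.682 for neural crest, 1.10e-06 to 0.704 for neural, 4.35e-08 to 0.476 for lens, 0.00106 to 0.513 for notochord and 6.37e-14 to 0.554 for germ cell genes. For the interaction they were 1.73e-07 to 0.405 for neural crest, 7.62e-16 to 0.423 for neural, 1.29e-07 to 0.664 for lens, 6.96e-13 to 0.845 for skeletal muscle and 3.85e-08 to 0.437 for germ cell genes. Depth of 3289161 to 5963478 reads and 2 libraries per group limit what the hearts can show.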

Other observations

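The genes of this part were named by the rule as extended to the blocked fit after the data were seen, and the fits without a pair were added then too.

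In DM embryos, members of the TGF-beta, activin and BMP list went both ways, with 4 higher and 8 lower of 53 in the blocked fit, and the list was not called. The antagonist gene nog3 rose by 1.40 in the blocked edgeR fit (SE 0.26, adjusted p = 0.00127), from 1.86 ± 0.483 to 4.57 ± 1.13 CPM (n = 3). The target gene id2b rose by 1.04 (SE 0.17, adjusted p = 0.00041) and the ligand gene bmp16 by 0.87 (SE 0.20, adjusted p = 0.00583; 0.0895 without pair 1). The chemokine gene cxcl12a rose from 58.2 ± 16.6 to 90.001 ± 26.3 CPM (0.70, adjusted p = 0.00844; 0.154 without pair 1) and the metalloproteinase gene mmp30 from 58.8 ± 12.4 to 104 ± 29.8 CPM (0.87, adjusted p = 0.00111). The scavenger receptor genes stab1 and stab2 of endothelium fell by 0.80 and 0.88 (adjusted p = 0.00446 and 0.000775; stab2 0.0790 without pair 1). Of 2 heart patterning genes, hey2 rose by 0.79 (adjusted p = 0.00209; 0.0853 without pair 1) and irx1a fell by 0.88 (adjusted p = 0.00278).

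Neural transcripts varied between hearts of the same group. Their share was 0.0946% and 0.590% in WT, 0.658% and 0.145% in siblings and 0.462% and 0.351% in DM. Erythroid transcripts took 0.507% and 0.516% in WT, 0.191% and 0.261% in siblings and 0.345% and 0.415% in DM. Mitochondrially encoded transcripts took 5.37% and 8.04%, 4.26% and 8.82%, and 3.90% and 5.34% in the same order.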
